A study of Mus musculus with 5 samples.

How the data were processed

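Gene expression was measured in 5 RNA samples from 3T3-L1 cells, a mouse fibroblast line that can be turned into fat cells in culture. Each sample was hybridised to 1 Affymetrix Clariom S mouse array. Per the labels' protocols, the cells grew for 4 days in basal medium. They then received an adipogenic mixture of 0.5 mM IBMX, 1 µM dexamethasone and 5 µg/mL insulin for 4 days, insulin alone for 2 days and basal medium for 1 day. The mature cells were then kept for 72 h in RPMI-1640 medium with 10% fetal bovine serum. In 3 samples (exposed), human MM.1S multiple myeloma cells shared that medium across a transwell membrane with 0.4 µm pores, so that secreted factors could pass but the cells were kept apart. In the other 2 samples (control) no myeloma cells were present. The labels count these as replicates of each group and do not say that they came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical. The labels state 50 ng of RNA per array. They speak of 10 isolated samples, while this series holds 5, and all 5 were analysed.

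The values are the deposited log2 expression values, 1 per probe set and array. They were made with RMA (background correction, quantile normalization and summary of the probes of a set) in Partek, per the submitters' processing notes; versions and the annotation build were not given in the sources used here. The table held 22206 probe sets with values from 1.20 to 13.2, and array medians from 4.80 to 4.88. A total of 6038 probe sets (27.2%) held exactly the same value on at least 2 of the 5 arrays. The table carried no detection calls, so no value could be marked as below background, and RMA compresses differences between dim signals. Precision is limited by the number of arrays. Gene symbols came from the platform annotation supplied with the table: 19572 probe sets had 1 symbol, 0 had several and 2634 had none. A RefSeq gene table of assembly GRCm38.p6 was used for older and current symbols only, and it updated 0 symbols. Several probe sets were found for 55 genes, 1 of them in a gene list. In the lists and among genes named whatever their result, the set with the highest mean over all arrays stood for its gene. Genes named by unadjusted p were taken from single probe sets, without that choice. No coordinates are given because the build of the array annotation was not stated.

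Exposed and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided) over all 22206 probe sets without a filter, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Residual degrees of freedom were 3 and the fitted prior added 3.17. Differences are exposed minus control on the log2 scale, with 95% intervals from the same fit. Group values are mean ± SD with n = 3 exposed and n = 2 control arrays. Each called or named value is limma's, and no count model was used.

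Before the data were examined, 31 gene lists were written from general knowledge of the cell type and treatment, holding 656 gene names, 1 of them (Gilz) an older name of a gene also listed (Tsc22d3). Of the genes, 591 were measured by a named probe set and 64 were not found under a current or older symbol and are not analysed here. The lists covered adipocyte identity, fatty acid and triglyceride synthesis, lipolysis and lipid droplets, fatty acid oxidation, cholesterol synthesis, senescence-associated secreted factors, NF-kB targets and acute phase, interferon response, cell cycle, p53 and senescence arrest, extracellular matrix structure, matrix remodelling, hypoxia and glycolysis, amino acid stress response, unfolded protein response, oxidative phosphorylation, thermogenic adipocyte, insulin and IGF signalling, adipokines and growth factors, glucocorticoid targets, NRF2 antioxidant, circadian clock, ribosomal proteins, lysosome and autophagy, and MHC class I. Markers of preadipocytes and fibroblasts, B and plasma cells, macrophages, endothelium, osteoblasts and skeletal muscle were included for other cell types. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists. The same lists were tested with an estimated correlation and with fry, which asks whether a list's own genes move one way and makes no comparison with other genes.

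The rule for named genes was also fixed beforehand. It takes up to 15 called genes per direction, or, where fewer pass, up to 5 per direction by unadjusted p, leaving out predicted genes. From each list it takes up to 4 called members or, where none passed, the 2 with the largest difference. Adipoq, Pparg, Fabp4, Plin1, Lep, Cebpa, Il6 and Cxcl12 were named whatever their result. Genes named outside this rule are said to be so.

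Distances between arrays were counted as probe sets more than 2-fold apart, and within-group and between-group pairs were compared by an exact permutation of the group labels. The alternatives were filters at the median and the 25th percentile of level, only probe sets with 1 symbol, a further quantile normalization, subtraction of array medians, trended and robust moderation, array weights, no moderation, stricter and looser thresholds, a block for replicate number, a block for neighbouring sample numbers in the titles, another rule for several probe sets, and leaving out each array in turn, where a lone control array was assumed to vary like the exposed ones. A test with each list's estimated correlation and the degrees of freedom of the preset test was added after the data were examined. The fit was tested on simulated data for this comparison, with 20 simulations of 22206 probe sets. In each, 200 probe sets were changed, in equal shares of 1.5-, 2-, 4- and 8-fold. It recovered 0.3% of genes changed 1.5-fold, 22.1% of those changed 2-fold, 88.1% of those changed 4-fold and 97.1% of those changed 8-fold, and 5.34% of all calls were false. With a simulated shift of -0.3 in the matrix structure list, camera recovered the list in 20 of 20 simulations and called 4 other lists over all of them. The simulated genes varied independently. The list's observed median shift was smaller, -0.13, and its estimated correlation was 0.29. The simulation therefore does not give camera's recovery or false calls at the observed setting. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.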

Results

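The arrays measured RNA of mature 3T3-L1 adipocytes kept for 72 h either with human MM.1S myeloma cells behind a porous membrane (3 exposed arrays) or in the same medium alone (2 control arrays). The comparison asks which adipocyte transcripts differ when myeloma cells share the medium without touching the adipocytes. Array medians lay between 4.80 and 4.88 on the log2 scale, and 5 arrays set the precision of every value below. Half-widths of the 95% intervals had a median of 0.41 over all 22206 probe sets.

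Adipocyte marker genes were at similar levels with and without myeloma cells. Fabp4, the fatty acid carrier of fat cells, had a log2 level of 12.37 ± 0.03 (SD, n = 3) on exposed and 12.37 ± 0.05 (SD, n = 2) on control arrays, with a 95% interval for the difference of -0.29 to 0.29. Adipoq, which encodes the hormone adiponectin, was at 11.57 ± 0.17 (SD, n = 3) against 11.58 ± 0.04 (SD, n = 2), an interval of -0.37 to 0.34. Pparg, the transcription factor that drives adipocyte differentiation, was at 10.99 ± 0.05 (SD, n = 3) against 10.97 ± 0.02 (SD, n = 2), an interval of -0.27 to 0.31. Cebpa, a second such factor, differed by -0.24 (-0.64 to 0.16) and Lep, the leptin gene, by -0.052 (-0.59 to 0.49) at a low level of 3.15 on exposed arrays. Plin1, which coats lipid droplets, differed by -0.25 (-0.87 to 0.37), and its exposed values were 9.86, 9.80 and 9.08 against control values of 9.90 and 9.77. Retn, the resistin gene, showed the widest difference of the list, 0.46 (0.056 to 0.86), and did not pass the test (limma adjusted p 0.93). Of the 18 measured adipocyte identity genes 8 were higher and 10 lower in mean, 0 passed over all genes and 0 when adjusted over the list alone. All 18 had an interval that excluded a 2-fold difference in either direction. Lep (mean 3.17) and Acvr1c (mean 2.60, named outside the rule) were dim, where RMA compresses differences. Their intervals limit the difference in array values and less so that in RNA.

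**Figure D1:**
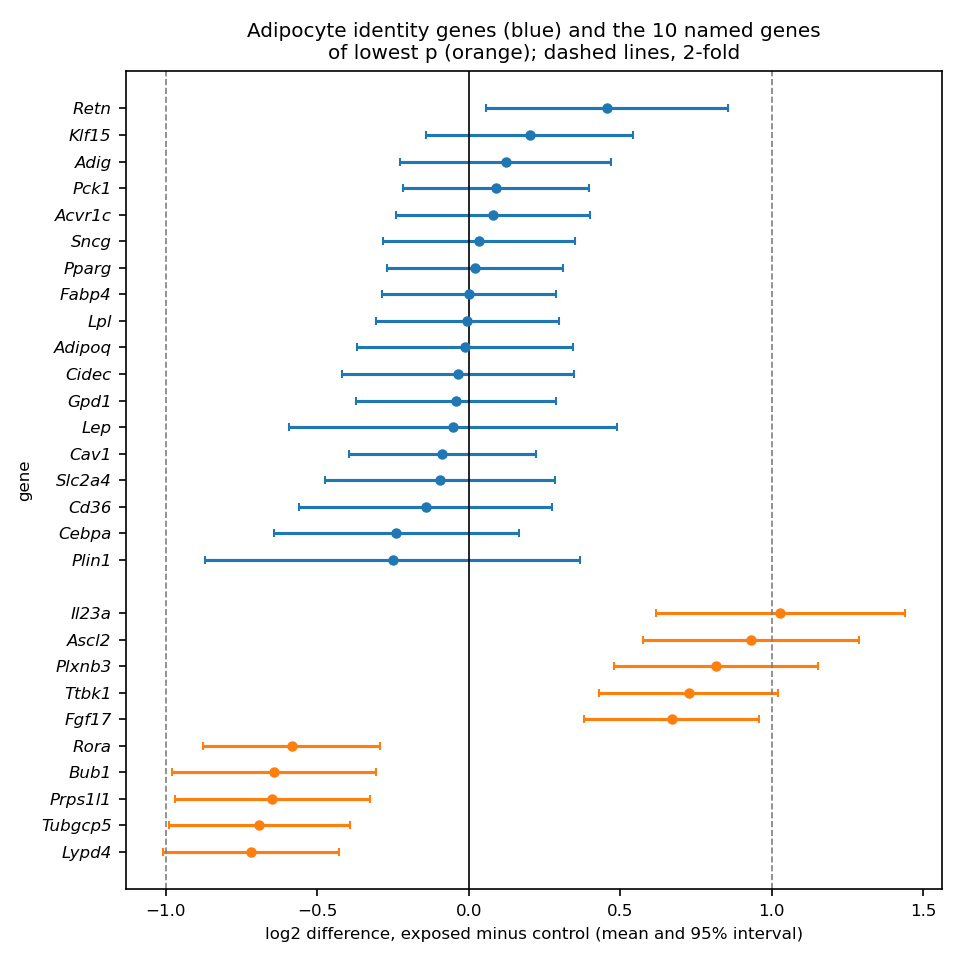
Points are log2 differences, exposed minus control, and bars are 95% intervals from limma, for the 18 measured adipocyte identity genes (blue) and the 10 genes of lowest unadjusted p that the naming rule took (orange); dashed lines mark 2-fold. The blue intervals all lie inside the 2-fold lines, while the interval of Il23a runs from 0.62 to 1.44, and 0 of the genes shown passed adjustment.

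No gene was called between exposed and control arrays. At an adjusted p under 0.05, limma called 0 of 22206 probe sets higher and 0 lower, and the smallest adjusted p was 0.93. The fit without moderation also called 0. In simulations that mixed 1.5-, 2-, 4- and 8-fold changes, limma recovered 22.1% of genes changed 2-fold. The larger changes there ease the adjusted threshold, and recovery without them was not simulated. The absence of calls alone therefore does not exclude 2-fold changes. At an unadjusted p under 0.05 there were 776 probe sets, 404 higher and 372 lower on exposed arrays, or 3.49% where chance alone gives 5% (1110 probe sets). Without control array 1 that count was 1378, in a fit with 1 control array left whose spread came from the exposed arrays alone. Of the 776, 65.9% lay below the median level. Among all probe sets, 1888 were higher and 1963 lower on every exposed array than on both control arrays, 17.3% in all, against 20% by chance. The interval excluded a 2-fold difference for 92.9% of probe sets, and for 96.1% of the 11103 in the upper part of the level range.

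The named genes of lowest unadjusted p were mostly dim and are given as values because none passed (limma adjusted p 0.93 for each). The naming rule took them only where exposed and control arrays did not overlap, so their separation is not a result. On the higher side, Il23a, which encodes an interleukin-23 subunit, was at 3.15 ± 0.22 (SD, n = 3) on exposed and 2.12 ± 0.11 (SD, n = 2) on control arrays, and the transcription factor gene Ascl2 was at 3.27 ± 0.06 against 2.34 ± 0.23. The kinase gene Ttbk1 differed by 0.73, the plexin gene Plxnb3 by 0.82 and the growth factor gene Fgf17 by 0.67. On the lower side, Bub1, a kinase of the mitotic checkpoint, was at 5.58 ± 0.12 (SD, n = 3) against 6.23 ± 0.12 (SD, n = 2). Tubgcp5, of the gamma-tubulin complex, was at 4.85 ± 0.01 against 5.54 ± 0.11. Lypd4 differed by -0.72, Prps1l1 by -0.65 and the nuclear receptor gene Rora by -0.59. The Rora probe set, which its name marks as unmapped, was dim (mean 2.76). A mean difference of more than 2-fold was found for 4 probe sets, of which 3 were named after their values were seen. These were the transcription factor gene Etv1 at 1.27 (0.57 to 1.96), the skin barrier gene Lce1d at 1.02 (0.46 to 1.58) and the uncharacterised D130040H23Rik at -1.22 (-2.28 to -0.16); the fourth was Il23a.

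Genes of the extracellular matrix lay slightly lower on exposed arrays as a group. In the matrix structure list, 28 of 32 measured genes were lower and 4 higher, with a median difference of -0.13. Tnc, the tenascin-C gene, was at 6.25 ± 0.19 (SD, n = 3) against 6.77 ± 0.003 (SD, n = 2), whereas Eln, which encodes elastin, differed by 0.48 in the other direction. In the matrix remodelling list, 16 of 21 genes were lower, with a median of -0.17, among them the cathepsin K gene Ctsk (-0.49) and the aggrecanase gene Adamts4 (-0.42). None of these genes passed singly, over all genes or adjusted over the list alone. Camera called both lists lower with its preset correlation, at an adjusted p of 0.0077 for matrix structure and 0.018 for matrix remodelling. Neither call held with an estimated correlation, where camera's adjusted p was 0.99 for matrix structure and 0.96 for matrix remodelling, and fry gave adjusted p-values of 0.94 and 0.49. The estimated correlation also lowers that test's degrees of freedom. The mean deviation of the matrix structure genes was -0.20 on exposed array 3, -0.00014 on exposed array 1 and 0.043 on exposed array 2, against 0.14 and 0.019 on the control arrays. Without exposed array 3 its median was -0.034 (camera adjusted p 0.28), and without control array 1 it was -0.084 (camera adjusted p 0.43, with 1 control array left and the spread from the exposed arrays alone). Without any other single array camera still called it, at medians from -0.19 to -0.17. Matrix remodelling genes were lower on every exposed array than on both control arrays in mean. The list lost the call without exposed array 1 (median -0.14, camera adjusted p 0.12). Without control array 1, which left 1 control array, its median was -0.13. With neighbouring title numbers as a block the call was also lost (camera adjusted p 0.17). That block leaves exposed array 1 without a partner, so its median is the same as without that array. A block for replicate number, described further below, ended the call of both matrix lists. Markers of preadipocytes and fibroblasts had a median of -0.13, with 12 of 15 lower (camera adjusted p 0.067).

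Senescence-associated secreted factors, NF-kB targets and p53 genes were split between higher and lower on exposed arrays. Most interferon response and cell cycle genes had a lower group mean on exposed arrays. None of these lists was called by camera with all 5 arrays equally weighted and no block. Of 28 measured senescence-associated secreted factors 12 were higher and 16 lower (median -0.039, camera adjusted p 0.96). Il6, the interleukin-6 gene, was at 4.95 ± 0.71 (SD, n = 3) against 5.45 ± 0.54 (SD, n = 2), and its interval of -1.55 to 0.56 did not exclude a 2-fold difference downwards. The chemokine gene Ccl20 differed by 0.60 (-0.19 to 1.38). NF-kB targets and acute phase genes were split 13 higher and 12 lower (median 0.025, camera adjusted p 0.98), with Bcl3 at -0.36 and Birc3 at -0.34. Genes of p53 and senescence arrest were 9 higher and 11 lower (median -0.013, camera adjusted p 0.93), including Plk2 at -0.36 and the death receptor gene Tnfrsf10b at 0.28. The interferon response list had 18 of 29 genes lower (median -0.11, camera adjusted p 0.055), with the antiviral gene Mx1 at -0.55 and Iigp1 at -0.49, and was not called. Its mean deviation was -0.091, -0.13 and 0.048 on exposed arrays 1 to 3, against 0.20 and -0.019 on control arrays 1 and 2. Cell cycle genes were lower for 22 of 27 (median -0.075, camera adjusted p 0.067), yet the checkpoint gene Bub1b differed by 0.40 while Bub1 differed by -0.64. The cell cycle deviations were -0.19, 0.037 and 0.028 on exposed arrays 1 to 3, against 0.099 and 0.023 on control arrays 1 and 2. Exposed and control arrays overlapped on the interferon and cell cycle lists. MHC class I genes had a median of -0.019 (camera adjusted p 0.96), with Psmb10 at 0.13 and H2-Q4 at -0.11.

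Medians of the fatty acid synthesis, lipolysis and fatty acid oxidation lists lay within 0.1 of 0. Most cholesterol synthesis and thermogenic genes had a higher group mean on exposed arrays, and most hypoxia and glycolysis genes a lower one. None of these lists was called by camera with all 5 arrays. Fatty acid and triglyceride synthesis genes were 9 higher and 12 lower (median -0.021, camera adjusted p 0.96). Within it the elongase gene Elovl6 differed by -0.48 (-1.10 to 0.15) and the acetyl-CoA carboxylase gene Acacb by 0.33. Lipolysis and lipid droplet genes were 5 higher and 10 lower (median -0.067, camera adjusted p 0.93), with the glycerol channel gene Aqp7 at -0.40 and the seipin gene Bscl2 at 0.34. Fatty acid oxidation genes were 14 higher and 8 lower (median 0.019, camera adjusted p 0.93), with Eci1 at 0.29 and Hadh at -0.37. The difference in Hadh came from exposed array 3, which read 8.47 where the mean of the other 4 arrays was 9.60. Cholesterol synthesis genes were higher for 15 of 19 (median 0.11, camera adjusted p 0.29), with Fdps and Dhcr7 each at 0.19, and were not called. Their mean deviation was -0.022, 0.16 and -0.045 on exposed arrays 1 to 3, against -0.0079 and -0.089 on control arrays 1 and 2. The higher group mean thus came from exposed array 2. The thermogenic adipocyte list was higher for 13 of 17 (median 0.18, camera adjusted p 0.080), at a low mean level of 4.26 and with a mean higher on every exposed array than on both control arrays, with the proton channel gene Otop1 at 0.60 and Tbx1 at -0.58. Hypoxia and glycolysis genes were lower for 25 of 30 (median -0.12, camera adjusted p 0.055), with Pdk1 at -0.36, although the lactate dehydrogenase gene Ldha differed by 0.28. The list's mean deviation was -0.037, 0.048 and -0.12 on exposed arrays 1 to 3, against 0.069 and 0.039 on control arrays 1 and 2. Oxidative phosphorylation genes were 15 higher and 17 lower (median -0.020, camera adjusted p 0.96), with Sdha and Ndufv2 each at -0.25.

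Secreted and signalling genes were likewise not called. Of 26 adipokines and growth factors 19 were lower (median -0.061, camera adjusted p 0.75). In mean they were lower on every exposed array than on both control arrays. Their fry p was 0.0053 and their fry adjusted p 0.17, the smallest of the 31 lists. Cxcl12, a chemokine that retains cells in the marrow, was at 9.75 ± 0.15 (SD, n = 3) against 9.99 ± 0.12 (SD, n = 2), an interval of -0.60 to 0.11, and the Wnt antagonist gene Sfrp5 differed by 0.66 at a low level. Insulin and IGF signalling genes had a median of 0.0079 (camera adjusted p 0.98), with Igfbp2 at 0.35 and Igf2 at 0.33. Glucocorticoid targets had a median of 0.11 (camera adjusted p 0.85), with Per1 at 0.33 and Tsc22d3 at -0.20. Circadian clock genes had a median of 0.050 (camera adjusted p 0.75), with Nr1d1 at 0.47 and Arntl, a gene that Nr1d1 represses, at -0.50. NRF2 antioxidant genes had a median of -0.014 (camera adjusted p 0.96), with Gpx2 at 0.49 and Osgin1 at 0.43. The amino acid stress response had a median of 0.014 (camera adjusted p 0.96), with Nars at -0.29 and Vldlr at -0.28. The unfolded protein response had a median of -0.054 (camera adjusted p 0.93), with Hyou1 at -0.29 and Xbp1 at -0.22. Ribosomal protein genes had a median of 0.0092 (camera adjusted p 0.96), with Rps19 at 0.17 and Rps7 at 0.14. Lysosome and autophagy genes had a median of -0.0047 (camera adjusted p 0.96), with Npc1 at -0.37 and Atp6v0d2 at 0.26.

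Markers of other cell types stayed at low levels in both groups, apart from preadipocyte and fibroblast markers, which fibroblast-derived cells express. B and plasma cell markers had a mean level of 3.66 and a median difference of -0.048 (camera adjusted p 0.96), with Cd79b and Mzb1 each at -0.37. The Cd79b difference came from control array 2, which read 3.47 where the mean of the other 4 arrays was 2.45. The array was made for mouse genes, so these levels do not tell whether RNA of the human myeloma cells was present. Macrophage markers had a mean level of 3.72 and a median of -0.027 (camera adjusted p 0.96), with C1qa at -0.51 and C1qc at 0.45. Endothelial markers had a mean level of 2.77 and a median of 0.046 (camera adjusted p 0.96), with Tie1 at -0.54 and Pecam1 at -0.32. Osteoblast markers had a mean level of 4.01 and a median of 0.058 (camera adjusted p 0.93), with Dmp1 at 0.29 and Sp7 at -0.28. Skeletal muscle markers had a mean level of 3.44 and a median of 0.095 (camera adjusted p 0.93), with Mylpf at 0.40 and Myh1 at 0.38. In the preadipocyte and fibroblast list, Cd24a differed by -0.43 and Pdgfrl by -0.38. Over all lists 0 genes passed when adjusted over the list alone, 4 of the 31 lists had means separated between the groups on every array, where chance gives 6.2, and camera with an estimated correlation called 0 lists.

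**Figure D2:**
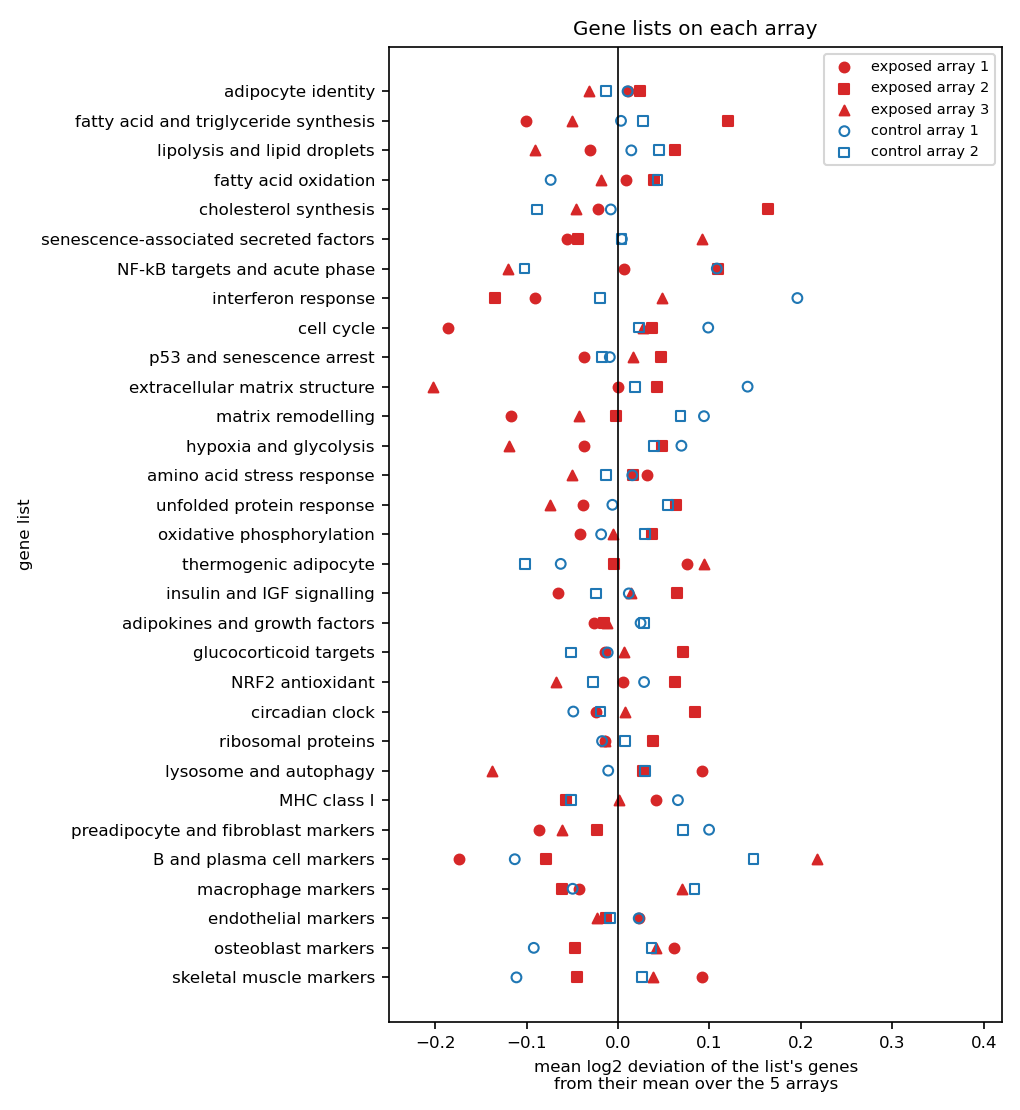
Each row is a gene list, and each point is the mean log2 deviation of its genes on 1 array from their mean over the 5 arrays (red filled, exposed; blue open, control). Matrix structure genes range from -0.20 on exposed array 3 to 0.14 on control array 1, and exposed and control points overlap in all but 4 of the 31 lists.

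By pairwise distance over all genes, exposed arrays were no farther from control arrays than arrays of a group were from each other. Pairs of arrays from different groups differed by more than 2-fold at 258 ± 92.8 probe sets (SD, 6 pairs), and pairs of the same group at 278 ± 100.1 (SD, 4 pairs). The difference between these means was -20.25, with a one-sided exact permutation p of 0.8 over the 10 possible splits, which cannot give a p below 0.1. The closest pair was control array 1 with exposed array 2, at 107 probe sets, and the farthest was exposed array 1 with exposed array 3, at 425. The first principal component, with 32.4% of the variance, set exposed array 1 at -28.8 and exposed array 3 at 29.6, with the other 3 arrays between -1.11 and 0.23. The second, with 29.1%, set exposed arrays 1, 2 and 3 at 21.4, -8.68 and 20.6, above control arrays 1 and 2 at -13.8 and -19.5; chance separates the groups on 20% of such components.

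**Figure D3:**
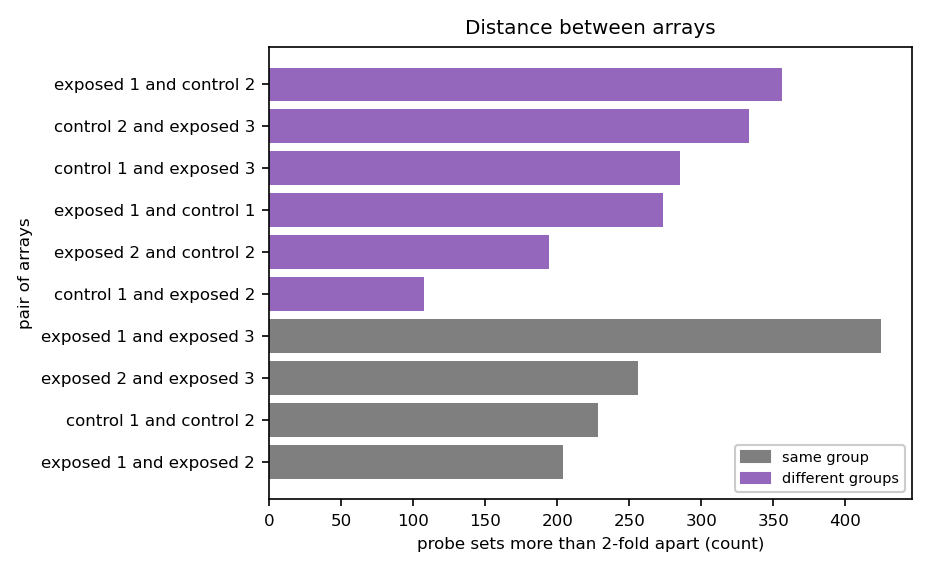
Bars give the number of probe sets more than 2-fold apart for each pair of arrays, in purple for pairs from different groups and in grey for pairs of the same group. Pairs from different groups span 107 to 356 and pairs of the same group 204 to 425.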

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

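All alternatives but 1 were fixed before the data were examined; the estimated correlation with the preset test's degrees of freedom was chosen after. The count of genes called was 0 under all of them except an unadjusted p under 0.05 with at least a 2-fold difference, which gave 4 genes, 3 higher and 1 lower. The count at an unadjusted p under 0.05 (776) was 362 with probe sets at or above the median level, where fewer were tested, and 760 to 1378 with 1 array left out, the highest without control array 1. Without a control array the lone control is assumed to vary like the exposed arrays. Of the 76 named genes 68 kept their sign throughout; Adipoq, Cd79b, Fabp4, H2-Q4, Hadh, Lep, Pparg and Tsc22d3 did not. Their lowest adjusted p from limma under any alternative was 0.76.

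The 2 list calls were less stable. With 1 array left out 0 to 4 lists were called, 0 without control array 1, 1 without exposed array 1 and 4 without exposed array 2 or control array 2. The estimated correlation, the same with the preset degrees of freedom, and fry each called 0, at a median of -0.13 for matrix structure and -0.17 for matrix remodelling, since they change only the test. With the replicate number as a block, which leaves exposed array 3 without a partner, camera called 1 list, the interferon response, and the medians were -0.034 for matrix structure (adjusted p 0.56) and -0.143 for matrix remodelling (adjusted p 0.068). Arrays of the same number did not vary together (residual correlations -0.014 and -0.032), so the numbers were not taken to pair them. Arrays with neighbouring title numbers gave 0.032 and 0.013, likewise near 0. The residuals of the 2 control arrays mirror each other, so these values are not independent checks. The block of neighbouring title numbers leaves exposed array 1 without a partner, and its medians are those without that array. It called 1 list, matrix structure (-0.174), with -0.141 for matrix remodelling (camera adjusted p 0.17). With 1 array left out the median ranged from -0.19 to -0.034 for matrix structure and from -0.21 to -0.13 for matrix remodelling. Camera's adjusted p for matrix structure ran from 0.00064 to 0.99 and for matrix remodelling from 0.0048 to 0.96 over the alternatives. Other than the smaller number of probe sets tested after the filter, the cause was not tested. Interferon response, cell cycle or hypoxia genes were called in 8 list results where they were not otherwise. Neither called list changed sign under any alternative, and the named genes that changed sign were uncalled in every fit. Dim probe sets carry no detection call, which limits what can be said of the genes at low level.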

Other observations

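The counts over splits and over intervals and the marker test below were chosen after the results they bear on had been seen, as was the use of the estimated correlation and of left-out arrays as tests of the matrix pattern.

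Single arrays carried isolated differences that group means spread over the group. A probe set was counted where 1 array lay more than 2-fold from the mean of the other 4 and those 4 spanned less than 0.5. There were 57 on exposed array 3, 55 on control array 2, 44 on exposed array 1, 17 on control array 1 and 10 on exposed array 2. On exposed array 3, Hadh, an enzyme of fatty acid oxidation, read 8.47 where the other 4 averaged 9.60 and spanned 0.022. On the same array Rab5b, an endosomal GTPase gene, read 5.55 against 6.77 and the survival gene Bcl2l1 read 5.39 against 6.55, while the GTPase gene Gpn1 read 7.96 against 6.87. On exposed array 1, Mtus1 read 6.25 against 7.44. These genes were chosen after their values were seen.

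No gene passed adjustment between exposed and control arrays, and differences of 2-fold in adipocyte identity genes, hidden by the spread between arrays, are argued against by the intervals, since 100% of the 18 measured genes had an interval that excluded them. For 14 of the 18 the interval also excluded a 1.5-fold difference, and for Cebpa, Lep, Plin1 and Retn it did not. For the dim genes Acvr1c and Lep, where RMA compresses differences, a larger difference in RNA is not excluded. The test over all probe sets would mostly not have called a 1.5-fold or a 2-fold change. Simulated beside larger changes, which ease the adjusted threshold, 0.3% of genes changed 1.5-fold and 22.1% of those changed 2-fold were recovered. As many probe sets as the 776 at an unadjusted p under 0.05 were found in 6 of the 10 splits of the 5 arrays, the real one included, and the highest other count was 1370, for exposed arrays 1 and 3 against the rest. With 10 splits a share under 0.05 cannot be reached.

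For the matrix structure and matrix remodelling lists, lower on exposed arrays by camera with the preset correlation, genes that vary together from array to array, whatever the group, are a candidate explanation. Camera was also run with each list's own estimated correlation and the preset test's degrees of freedom. By it matrix structure (correlation 0.29) had an adjusted p of 0.76 and an unadjusted p of 0.19. Matrix remodelling (0.057) had 0.155 and 0.015, which leaves this explanation open for that list. Preadipocyte and fibroblast markers (0.0080) and thermogenic genes (0.011) had smaller unadjusted p-values by it, also at an adjusted p of 0.155. Their estimated correlations were negative (-0.034 and -0.041), so the test treated their genes as uncorrelated. Single arrays may also set the matrix structure shift: without exposed array 3 the adjusted p was 0.28 and the median -0.034, while without exposed array 1, exposed array 2 or control array 2 the list was still called at -0.174, -0.184 and -0.185, and the fit without control array 1 (0.43) rests on 1 control array. A smaller share of undifferentiated cells on the exposed arrays would lower preadipocyte and fibroblast markers too; their median was -0.128, lower on every exposed array in mean, but that list was not called (camera adjusted p 0.067), so such a share cannot be told apart from spread between 5 arrays. An effect of the myeloma cells on matrix genes stays open and was not tested separately from these.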
